A study of Halobacterium salinarum NRC-1 with 322 samples.

How the data were processed

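Growth and regulation in Halobacterium salinarum NRC-1 were measured on 2-colour spotted oligonucleotide arrays. Per the labels, total RNA of each culture was hybridised against a common reference made from wild type cells in mid-log phase, on 2 arrays with the dyes exchanged, so that 322 arrays stand for 161 cultures. RNA was prepared with a miniprep kit and checked for DNA and integrity, per the labels' protocols. The scanner, the background correction, the normalization within arrays and the treatment of weak spots are not given in the sources used here.

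The deposited table holds 1 log ratio per spot for 10752 spots on each array, and its values are taken here as log10, the unit that their spread fits. The log base is not stated in the sources used here, so every log2 value would scale by one factor under another base, and counts at a minimum of 2-fold would change, while signs, tests and counts without a minimum fold would stay as they are. Values were divided by the log10 of 2 and are reported as log2 ratios. Median log2 ratios per culture lay between -0.29 and 0.48 with an SD of 0.10, and whether values were centred before deposit is not given in the sources used here. The direction of the deposited ratio is not stated either. It was read as channel 1 over channel 2, and this direction is likely rather than settled. Its basis is pyrF, the gene known as ura3 in the labels, which with this reading lies lower in the ura3 strain than in the wild type (-0.70, limma adjusted p = 0.0907, not past the threshold) and higher in the vector strain than in the ura3 strain (0.61, adjusted p = 0.0118). That second call comes from strains that share no run and was lost with run as a random block (adjusted p = 0.136), though not with runs 3 and 4 as 1 block (adjusted p = 0.0232). Its ura3 side holds a pyrF value from only 1 culture of run 2 and 5 of run 4. With the opposite reading the sign of every ratio and difference would turn, while correlations and covariances between them would not.

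Each probe has 4 spots on the array. A table of platform annotation pairs 532 spots with 133 gene symbols, and in all 133 the 4 spots follow one layout, which was used to group the other spots into 2688 probes. No spot carries several symbols, and 10220 spots carry none and are given by the number of their first spot. The general transcription factor genes (tbp and tfb) carry no symbol in that table, so the deleted or expressed gene could not be followed in its own strain and the strain labels were not checked in that way. Exact zeros make up 13.2% of the values, from 0 to 53.7% of an array. All 4 spots of a probe were at 0 on an array in 6.77% of cases, against 0.276% if zeros fell at random, so zeros were treated as not measured. The number of arrays limits the precision, and the median SD between the spots of a probe was 0.18.

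The sign of arrays with culture RNA in channel 2 was turned, spots were averaged, and the 2 arrays of a culture were averaged to 1 value, so the culture is the replicate. The 2 arrays of a culture had a median correlation across probes of 0.708 after turning and removal of the dye effect, and 2 cultures had a value below 0, tbpA deletion replicate 1 (-0.302) and tfbA expression replicate 3 (-0.068). Both were kept, and without the first the tbpA deletion has 124 calls in place of 63. The late minus early differences of the 2 dye orientations, before turning, correlated at -0.776 in run 1, -0.108 in run 2, -0.94 in run 3, -0.896 in run 4 and -0.794 in run 5, where opposite signs are needed for a dye exchange, so run 2 carries the weakest check of orientation. In 1 culture (tfbA expression replicate 7) both arrays ran opposite to the other cultures of their run and stage at a correlation under -0.3. Its direction has no settled reading, and it was kept as labelled. Values without it and with its sign turned are given for the growth stages, the interaction, run 1 alone, the run 1 strains and deletion counts that moved.

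Cultures were placed in groups by strain from the titles, and in 3 growth stages by the optical density (OD600) in the titles, with bounds at 0.3 and 0.6. Early cultures lay between 0.132 and 0.225, mid cultures between 0.376 and 0.496 and late cultures between 0.749 and 1.114. From the array numbers in the titles and the kind of strain, 5 runs were set before the data were examined and treated as batches, and a strain in 2 runs was fitted as 2 groups. Runs 3 and 4 follow each other without a gap in the numbers, and their border is where the plasmid-bearing strains end. Gaps inside runs 1 and 4 were not used as borders, although some inside run 1 are wider than that between runs 4 and 5. Whether these runs are true batches is not given in the sources used here. Labels gave no strain for 3 cultures and the tbpB deletion had 1 culture, so these 4 stayed out of every comparison. The series description tells of biological duplicates followed along the growth curve. Cultures of different stages may therefore come from one flask, and p-values then measure only the spread between these samples and may be too small.

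Probes with a value in at least 80% of 157 cultures were tested, 2085 in all, of which 122 have a symbol. One limma fit (lmFit, contrasts.fit and eBayes) held 26 strain and run groups plus growth stage as an additive term. Benjamini-Hochberg adjustment was made within each comparison with a threshold of 0.05, and every adjusted p of a probe given below comes from limma. Errors of log2 differences are the SE of that fit. Deletion strains were compared with the ura3 strain of their run, and expression strains with the vector strain of their run. The 5 expression strains of run 1, which holds no control strain, were compared with the vector cultures of runs 3 and 5. An F-test over all strain by stage terms gave the interaction. The median residual SD was 0.18.

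Gene lists were fixed as 31 patterns on symbols before the data were examined, as were the comparisons and the rule for naming genes. Of these, 9 lists had at least 4 named members and were tested with limma's camera at a preset correlation of 0.01, adjusted within each family of comparisons, with an estimated correlation and fry as alternatives. They are chemotaxis, purine synthesis, pyrimidine synthesis, cobalamin synthesis, the tricarboxylic acid cycle, tRNA synthetases, other rhodopsins, chaperones and proteases, and DNA replication and repair. The pattern for tRNA synthetases also took glmS, and the pattern for chaperones and proteases took panB, neither of which belongs there by function. The transducer genes htr1 and htr2 are in 2 of the lists. The naming rule took, for the growth stages and controls, the 10 symbols with the largest rise and the 10 with the largest fall among called probes whose dye orientations shared a sign. For a strain it took 3 each way, plus up to 4 members per passing list and up to 10 symbols called in the most strains of a kind. Genes chosen after their values were seen are marked where they appear.

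The fitting code was tested on simulated data with the real layout and spread, after the fit had first been run on the real data. In the simulated late against early comparison, 100% of 100 probes changed by 0.5 on the log2 scale were recovered, and in the tbpA deletion 76%, out of 2085 probes. At a change of 1, 97% to 100% were recovered in the 6 comparisons simulated, and 2.02% to 7.14% of calls were false. The simulated noise was independent between probes and cultures. These shares therefore leave out false calls from a culture that is off at many probes together. In the simulated list test the moved list, chemotaxis, was called, and so was 1 list that was not moved as a whole, other rhodopsins, where 2 of 5 members are shared with it (adjusted p = 0.000551). Standard errors from each probe's own cultures were tried for the reported values after the limma counts had been seen, and the reported values were then returned to the limma functions fixed before the data were examined. The version tried gives 58 calls in the tbpA deletion and 99 in the tfbB deletion and stands as an alternative.

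Alternatives covered centring with quantile normalization, each dye orientation alone, OD600 as a curve, cell means per strain and stage, other choices of control, separate fits, array weights, medians of spots, a minimum fold and each culture left out in turn. Chosen after seeing the data were zeros kept as values, fits without 2 unusual cultures, 1 culture with its sign turned, runs 3 and 4 as 1 random block, lists within runs with an estimated correlation, comparisons within run 1 without that culture, exact standard errors, wild type alone, each run alone and each run or the wild type held out. The wild type alone was read from a fit of all cultures with a mean per strain and stage, with the spread of all strains. Each run alone was fitted on its own cultures. The versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No genome build was needed, and gene positions were not used here.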

Results

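Transcript levels of Halobacterium salinarum NRC-1 were measured along the growth curve in 25 strains. These are the wild type, a strain without ura3 that is the parent of the deletion strains, a vector control that carries a plasmid expressing only the c-Myc tag, strains that lack a general transcription factor, and strains that express a c-Myc tagged factor from the plasmid. The factors are the TATA-binding proteins (tbpA to tbpF) and the TFB proteins (tfbA to tfbG), which recruit RNA polymerase to promoters. The 98 plasmid-bearing cultures grew with 20 µg/ml mevinolin and the other 63 without it. The 161 cultures comprise 51 early, 51 mid and 59 late cultures by OD600, and most strains have 6 cultures, 2 per stage. Run 1 of the arrays holds the tfbA, tfbB, tfbC, tfbF and tfbG expression strains, with 8, 8, 7, 8 and 6 cultures, and no control. Run 2 holds the tbpA, tbpC, tbpD and tfbD deletions with 6 cultures each, the tfbB deletion with 5 and 3 ura3 cultures. Run 3 holds the tbp expression strains with 6 cultures each (tbpC has 5) and 6 vector cultures. Run 4 holds the tfbA and tfbC deletions, the ura3 strain and the wild type with 6 cultures each and the tfbE deletion with 5. Run 5 holds the tfbD and tfbE expression strains and the vector control, with 6 each. All values are log2 ratios of culture over reference or differences of such ratios, and errors are SE unless stated. Their direction is likely but not settled, as given with the processing.

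The first comparison asked which transcripts change as cultures become dense. It set 58 late against 50 early cultures. The largest differences were at unnamed probes, which rose at spots 1605 (3.07 ± 0.14) and 5053 (2.11 ± 0.10) and fell at spots 3133 (-1.78 ± 0.091) and 369 (-1.63 ± 0.096), chosen after their values were seen. The largest falls among named genes were in rpl12p, a ribosomal stalk protein (-1.46 ± 0.082), rpmC, a protein of the large ribosomal subunit (-1.19 ± 0.072), and eno, the glycolytic enzyme enolase (-1.14 ± 0.057). The glutamate dehydrogenase gene gdhA2 (-0.88 ± 0.042), the translocase gene secY (-0.87 ± 0.059), the cytidylate kinase gene cmk (-0.83 ± 0.041) and speB, an agmatinase (-0.78 ± 0.041), fell as well. So did lysS, lysyl-tRNA synthetase (-0.74 ± 0.036), ndk, nucleoside diphosphate kinase (-0.66 ± 0.037), and mdh, malate dehydrogenase (-0.65 ± 0.043). The largest rises among named genes were in argH, the last enzyme of arginine synthesis (1.20 ± 0.059), and pan1 (1.00 ± 0.072). The thiamine synthesis genes thiD (0.83 ± 0.087) and thiC (0.65 ± 0.069), the cobalamin gene cbiT (0.78 ± 0.070), and the purine genes purL (0.69 ± 0.047) and purF (0.63 ± 0.051) rose too. The signal transducer genes htr6 (0.65 ± 0.031) and htr1 (0.61 ± 0.034) rose, as did hisG, the first enzyme of histidine synthesis (0.65 ± 0.039). In the fits per strain, rpl12p, rpmC, eno and secY were lower in late than in early cultures in 26 of 26 strain and run groups, and argH, hisG, purL, purF, htr6 and htr1 were higher in 26 of 26. In all, limma called 1688 of 2085 probes, 794 higher and 894 lower, and 73 of them changed at least 2-fold.

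Between early and mid cultures (n = 50 and 49) the arginine fermentation genes fell furthest among named genes, while an unnamed probe at spot 2583, chosen after its value was seen, fell more than arcA (-1.19 ± 0.096). The carbamate kinase gene arcC changed by -1.42 ± 0.094 and the arginine deiminase gene arcA by -1.01 ± 0.073, and in late cultures both lay closer to the early level (-0.47 ± 0.090 and -0.31 ± 0.070). The mean ratio of arcC over the reference was 1.03 ± 0.47 (SD, n = 50) in early, -0.39 ± 0.41 (n = 49) in mid and 0.61 ± 0.62 (n = 58) in late cultures. Smaller falls by mid phase were in rpl12p (-0.33 ± 0.085), orc8, a replication initiation gene (-0.29 ± 0.035), trpC of tryptophan synthesis (-0.27 ± 0.073), gdhA2 (-0.27 ± 0.043) and eno (-0.27 ± 0.060). The initiation factor gene infB (-0.22 ± 0.035), secY (-0.22 ± 0.062) and the glutamine synthetase gene glnA (-0.22 ± 0.026) also fell. The largest rises were at the unnamed spots 4795 (1.01 ± 0.064) and 2301 (1.01 ± 0.071), chosen after their values were seen. Cobalamin and nucleotide synthesis led the rises among named genes, with cbiT (0.95 ± 0.073), cbiG (0.63 ± 0.050), cobN (0.50 ± 0.057), purL (0.76 ± 0.048), purF (0.49 ± 0.053), purM (0.46 ± 0.039) and carB, carbamoyl phosphate synthase (0.61 ± 0.087). The other rises were in argH (0.48 ± 0.062), ppsA, phosphoenolpyruvate synthase (0.44 ± 0.065), and pan1 (0.43 ± 0.075). limma called 1040 probes, 364 higher and 676 lower. With arrays centred and quantile normalized, 597 were called, 300 higher and 297 lower. For the wild type 93 probes passed, in a fit of all cultures with the spread of all strains. In run 1 fitted alone 82 passed (273 without tfbA expression replicate 7, and 252 with its sign turned) and in run 3 alone 489. Signs turned for pan1 in the wild type (-0.061) and run 5 (-0.14) and for carB in runs 2 and 4 (-0.19 and -0.16). They also turned for ppsA in run 2 (-0.019) and trpC in run 1 (0.0097).

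**Figure D1:**
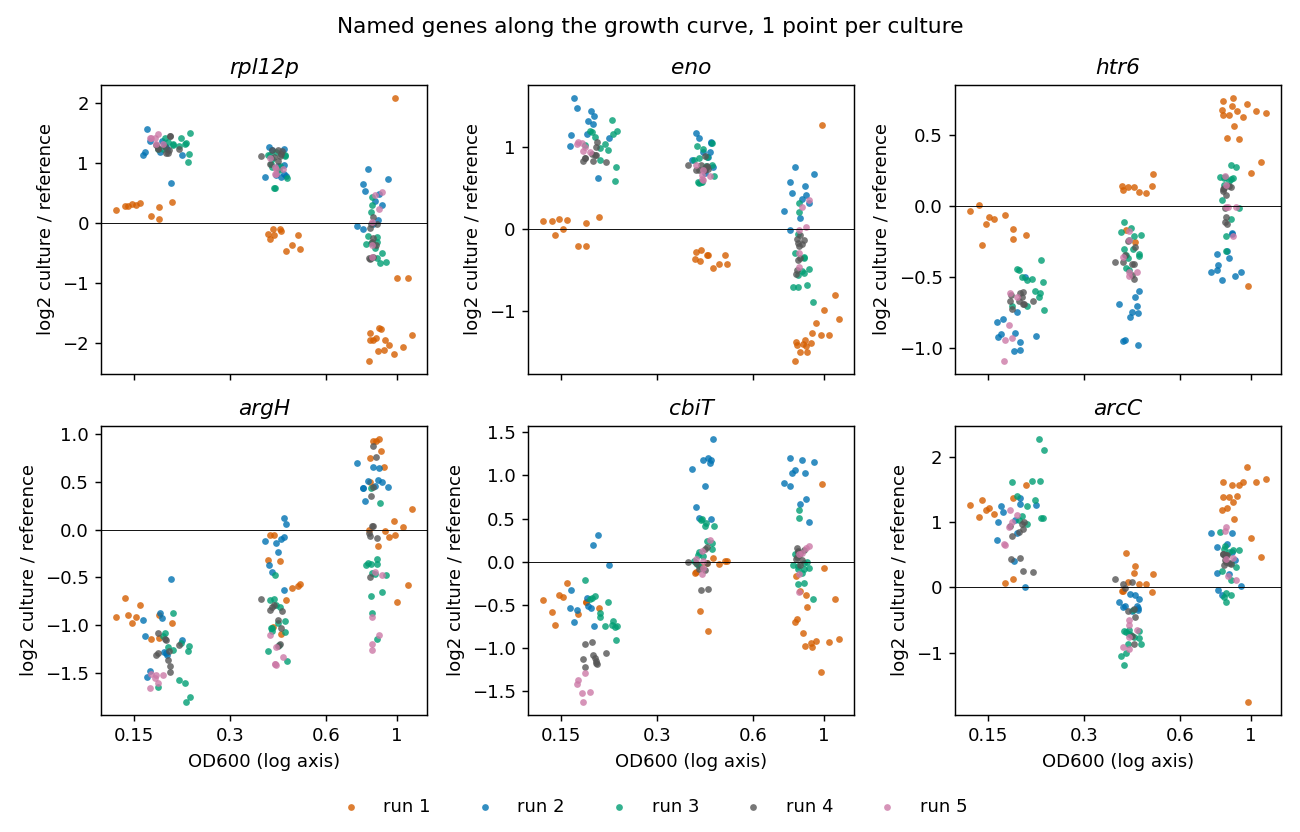
Log2 ratio of culture over reference for 6 named genes against the OD600 of the culture on a log axis, 1 point per culture, coloured by array run. The plot shows rpl12p and eno falling, htr6 and argH rising, cbiT rising by mid phase and arcC lowest in mid cultures. Early and mid run 1 points lie below the other runs for rpl12p and eno and overlap them for cbiT, arcC and argH, and for rpl12p and eno 1 late run 1 culture (tfbA expression replicate 7) lies opposite to the others.

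Of the fixed gene lists, chemotaxis genes rose together by late phase. Of 10 measured members 8 rose, among them htr6, htr1, cheA (0.51 ± 0.035), a kinase, and cheY (0.41 ± 0.030), its response regulator, 1 fell and 1 was not called. The list test gave an adjusted p of 0.00565, and adjusted p = 0.25 with an estimated correlation, and 9 members passed adjusted over the list alone. By mid phase 6 of the 10 rose and 4 were not called (adjusted p = 0.00565, and adjusted p = 0.25 with an estimated correlation), 6 adjusted over the list alone. All 4 cobalamin genes, cbiT, cbiG, cobN and cbiQ (0.34 ± 0.030), rose by mid phase (adjusted p = 2.01e-08), and 4 passed adjusted over the list alone. This call held with an estimated correlation (adjusted p = 0.012). By late phase the same 4 were higher than in early cultures (adjusted p = 0.039, and adjusted p = 0.37 with an estimated correlation), 4 adjusted over the list alone, a call that ended without tfbA expression replicate 7 (adjusted p = 0.0561). Among 6 purine synthesis genes 5 rose and 1 fell by mid phase (adjusted p = 7.72e-07), 6 adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 0.026). By late phase it was again 5 and 1 (adjusted p = 0.039, and adjusted p = 0.37 with an estimated correlation), 6 adjusted over the list alone, which also ended without that culture (adjusted p = 0.0561). In both the gene that fell was guaB (-0.23 ± 0.038 in late cultures), which makes guanine nucleotides from inosine monophosphate.

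Of 5 pyrimidine synthesis genes, 3 rose by mid phase, carB, pyrI (0.20 ± 0.048) and carA (0.14 ± 0.044), and 2 were not called (adjusted p = 0.039, and adjusted p = 0.25 with an estimated correlation), 4 adjusted over the list alone. Without tfbA expression replicate 7 this call ended too (adjusted p = 0.0538). In single runs carA turned sign in runs 2 and 4 (-0.28 and -0.057) and pyrI in run 1 (-0.11). By late phase 1 of the 5 fell (adjusted p = 0.903). In the tRNA synthetase list 10 of 13 fell by late phase, 2 were not called and 1 rose (adjusted p = 0.0153, and adjusted p = 0.25 with an estimated correlation), 11 adjusted over the list alone. Examples are lysS, proS (-0.55 ± 0.025), aspS (-0.44 ± 0.024) and cysS (-0.42 ± 0.029). The gene that rose, glmS (0.30 ± 0.033), makes glucosamine 6-phosphate and charges no tRNA. All 6 genes of the tricarboxylic acid cycle fell by late phase, but the list did not pass against other genes (adjusted p = 0.099), and 6 passed adjusted over the list alone. The lists of other rhodopsins (3 rose, 2 fell, adjusted p = 0.198), chaperones and proteases (2 rose, 4 fell, adjusted p = 0.405) and DNA replication and repair (1 rose, 3 fell, adjusted p = 0.571) did not pass by late phase either.

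The late response was also read within each array run and in the wild type. Fitted alone, runs 1 to 5 gave 1280, 1458, 1454, 1641 and 1460 called probes. With each run held out in turn, a check chosen after seeing the data, between 83.0% and 95.1% of the probes called on the other runs had the same sign in the run held out, against 49.9% to 50.3% for independent signs. For the 6 wild type cultures limma called 964, in a fit of all cultures with a mean per strain and stage. Its error came from the spread of all strains, so this is no test within the 6 cultures alone. Of 1677 probes called without the wild type, 1567 (93.4%) had the same sign in it, against 50.2% for independent signs. Chemotaxis passed as a rising list in each of the 5 runs (highest adjusted p = 0.0447). The tRNA synthetase list passed in runs 1, 3, 4 and 5 but not in run 2 (adjusted p = 0.389), and purine synthesis in run 2 alone (adjusted p = 0.0143, and from 0.141 to 0.144 in the others). Cobalamin synthesis passed in runs 2 to 5 and was turned in run 1 (median -0.11, adjusted p = 0.798). There thiD (-0.34, adjusted p = 0.00209), cbiT (-0.12), thiC (-0.11), cbiG (-0.12) and cbiQ (-0.10) were negative. Without tfbA expression replicate 7 these 5 were -0.41, -0.21, -0.18, -0.18 and -0.14, and with its sign turned -0.38, -0.22, -0.18, -0.17 and -0.14. The run 1 count was then 1464 and 1444, the cobalamin median -0.16 in both, and 83.7% and 82.6% of the probes called on the other runs had the same sign in run 1. The lists of chemotaxis, tRNA synthetases and the tricarboxylic acid cycle passed in the same runs either way. The tricarboxylic acid cycle passed as a falling list in runs 1 and 3 (median -0.77 and adjusted p = 0.00779, and adjusted p = 0.0437), but not in runs 2, 4 and 5 (adjusted p = 0.870, 0.159 and 0.609). These list tests within runs used the preset correlation, and with an estimated correlation none of the 45 passed (lowest adjusted p = 0.352). The growth response differed between strain and run groups for 1172 of 2085 probes (F-test of the interaction in limma, 1306 at an unadjusted p under 0.05), 86 of them named. Without tfbA expression replicate 7 this count was 1675, and with its sign turned 1644. The late and mid counts became 1703 and 1098 without it, and 1701 and 1083 with its sign turned. In either case 5 list tests of the growth stages passed in place of 8, since purine and cobalamin synthesis by late phase (adjusted p = 0.0576 with the sign turned) and pyrimidine synthesis by mid phase (adjusted p = 0.0528) no longer passed. With OD600 as a curve the same 3 tests did not pass (adjusted p = 0.0601, 0.0601 and 0.106).

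The strain without ura3 was set against the wild type in run 4 (n = 6 and 6) to show what the parent of the deletion strains carries. No named gene passed. The pyrF gene, which encodes the orotidine phosphate decarboxylase of pyrimidine synthesis and was used to set the direction of the ratios, lay at -0.70 ± 0.20 (adjusted p = 0.0907). It had a value in 5 cultures of each strain. limma called 10 probes of 2085, 4 higher and 6 lower, against 104 at an unadjusted p under 0.05. The largest differences were in 2 probes without a symbol, named by their first spot, 4433 (-2.02 ± 0.17) and 5161 (-1.57 ± 0.20), chosen after their values were seen. None of the 9 lists passed (adjusted p = 0.859 for each).

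The vector control was set against the ura3 control (n = 12 and 9, each over 2 runs). The direction of all ratios was set by pyrF, so its sign here is no independent finding. It had a value in only 1 ura3 culture of run 2 and 5 of run 4, and in 5 and 6 vector cultures of runs 3 and 5. pyrF was higher in the vector strain (0.61 ± 0.19, adjusted p = 0.0118), as were the purine gene purE (0.24 ± 0.067), htr6 (0.23 ± 0.072), ndk (0.22 ± 0.086) and gatA, a subunit of a tRNA amidotransferase (0.21 ± 0.053). The proteasome gene psmA (0.20 ± 0.070) and the export gene secF (0.13 ± 0.048) were higher too. Lower were cbiT (-0.70 ± 0.16), rpmC (-0.70 ± 0.17), argH (-0.56 ± 0.14), gdhA1, a glutamate dehydrogenase (-0.50 ± 0.19), and mvk, the mevalonate kinase of isoprenoid synthesis (-0.44 ± 0.075). So were hisD of histidine synthesis (-0.44 ± 0.090), gdhB (-0.40 ± 0.12), the chaperone gene dnaK (-0.39 ± 0.088), phnE (-0.39 ± 0.072) and pheA of phenylalanine synthesis (-0.38 ± 0.078). limma called 580 of 2065 probes, 227 higher and 353 lower, including 7 named genes higher and 29 lower, and no list passed (adjusted p = 0.859 for each). Plasmid-bearing and plasmid-free strains shared no run, and only the former grew with mevinolin, so plasmid, mevinolin and run cannot be told apart fully. With run as a random block 45 probes passed and mvk was the only one of these 17 named genes that did (adjusted p = 0.0405). Runs 3 and 4 follow each other in array number and their border was set by the kind of strain. With these 2 as 1 block, chosen after seeing the data, 111 probes passed and pyrF, mvk, hisD and phnE did (highest adjusted p = 0.0397, and 0.0232 for pyrF). Against the ura3 cultures of run 2 the run 3 and run 5 vector cultures gave 725 and 781 calls, against those of run 4 only 53 and 28, where ndk (-0.10), cbiT (0.075) and gdhA1 (0.056) turned sign for run 3 and hisD (0.011) for run 5. Centred and quantile normalized arrays gave 464 calls, 273 higher and 191 lower.

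**Figure D2:**
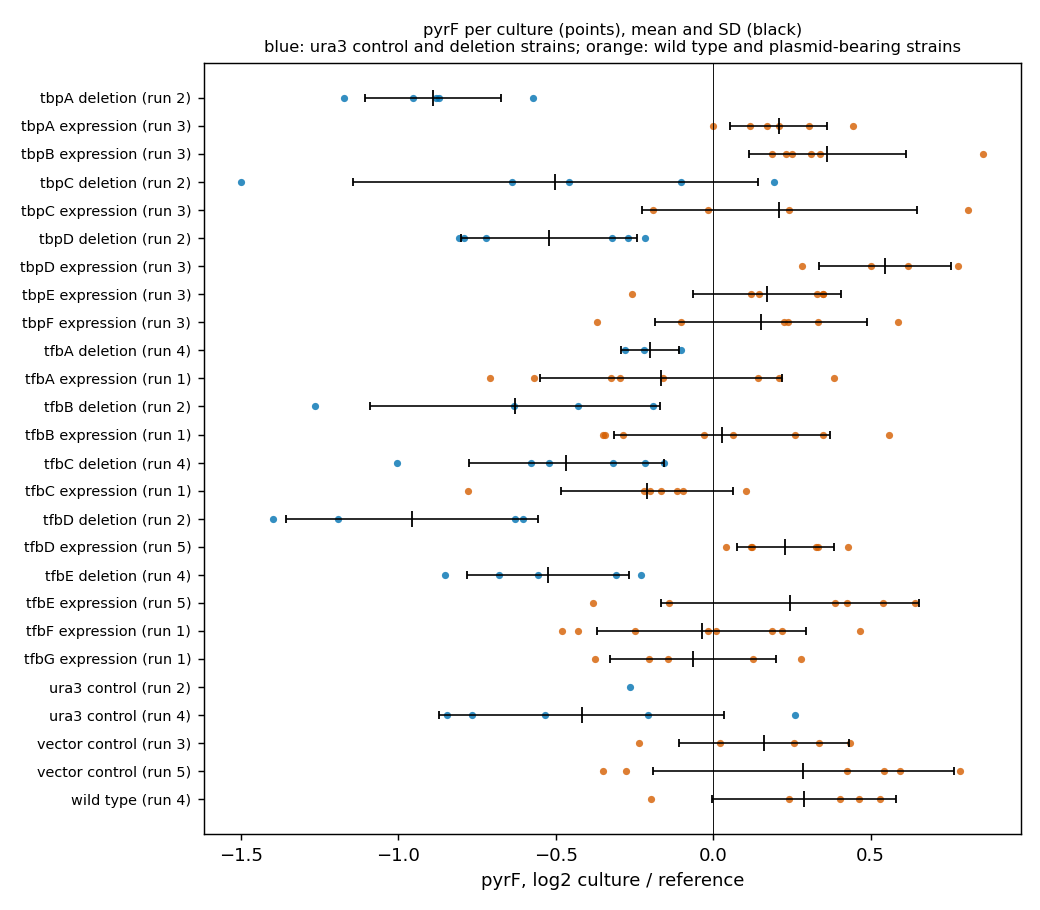
Log2 ratio of pyrF over the reference in each culture (points) with the mean and SD (black), by strain and array run. The ura3 control of run 4 (mean -0.42) and all deletion strains derived from it (means from -0.95 to -0.20) lie below the wild type (0.29) and the vector controls (0.16 and 0.29). This gene was used to set the direction of the ratios, so which side is lower was fixed by that choice.

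Deletion of tfbC changed the most named genes among the deletion strains (n = 6 and 6 ura3 cultures of run 4). The chemotaxis genes cheR, a methyltransferase of receptors (0.45 ± 0.087), cheA (0.36 ± 0.10), cheB (0.32 ± 0.091) and cheY (0.30 ± 0.088) were higher, as was hisF of histidine synthesis (0.41 ± 0.087). pyrI, the regulatory subunit of aspartate carbamoyltransferase, was lower (-0.44 ± 0.14). With each of the 12 cultures left out in turn, cheR and hisF passed in 12 of 12 fits, cheB in 8, cheA in 6, cheY in 5 and pyrI in 2. Of 10 chemotaxis genes 4 rose and 6 were not called (adjusted p = 0.0153, and adjusted p = 0.928 with an estimated correlation), 4 adjusted over the list alone. Against the other deletion strains of run 4, without its controls, cheR (0.32 ± 0.077), cheA (0.29 ± 0.092), cheY (0.25 ± 0.078) and hisF (0.42 ± 0.076) were higher as well. There cheB and pyrI were not called. limma called 68 of 2085 probes, 53 higher and 15 lower, with the largest differences at the unnamed spots 1541 (1.63 ± 0.14) and 1547 (-2.43 ± 0.21). The other deletions of run 4 called few probes. The tfbA deletion had 5 lower and 53 at an unadjusted p under 0.05, led by the unnamed probe at spot 2611 (-0.97 ± 0.097), and the tfbE deletion had 2 higher and 46 at an unadjusted p under 0.05, at spots 2681 (0.56 ± 0.13) and 1637 (0.53 ± 0.11). These spots were chosen after their values were seen. Leaving out tfbA deletion replicate 3 gave 3 calls there, and in the tfbE deletion ura3 replicates 1, 3 and 4 gave 1, 0 and 0, its own replicates 1 and 2 gave 1 and 0, and replicate 5 gave 5.

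In run 2 the deletion strains were compared with 3 ura3 cultures that all 5 strains share, so the strains are not independent of each other. In the tfbD deletion (n = 6) purM of purine synthesis was higher (0.47 ± 0.14, adjusted p = 0.0409), and purF (0.48 ± 0.19), purL (0.40 ± 0.17) and purE (0.27 ± 0.10) were not called. Of 6 purine genes 1 rose and 5 were not called (adjusted p = 1.35e-06, and adjusted p = 0.233 with an estimated correlation), and 5 passed adjusted over the list alone. The purine list also passed in the tbpA, tbpD and tfbB deletions (adjusted p = 0.0153 in each, and adjusted p = 0.928 with an estimated correlation), with 0 of 6 members called by limma in any of them and 0 adjusted over the list alone. There purM lay at 0.30 ± 0.14, 0.28 ± 0.14 and 0.29 ± 0.14, with list medians of 0.16, 0.12 and 0.19. In the tfbB deletion (n = 5) secF was higher (0.26 ± 0.077), and nadC of NAD synthesis (-0.52 ± 0.16) and aroC, the last step of chorismate synthesis (-0.27 ± 0.087), were lower, each passing in 3 of 8 fits with a culture left out.

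Most calls in run 2 were lower. limma gave 112 in the tfbB deletion (5 higher, 107 lower), 63 in the tbpA deletion (0 higher, 63 lower), 57 in the tfbD deletion (4 higher, 53 lower), 9 in the tbpD deletion (0 higher, 9 lower) and 2 in the tbpC deletion (0 higher, 2 lower). At an unadjusted p under 0.05 the counts were 399, 303, 335, 207 and 88. No named gene passed in the tbpA, tbpC or tbpD deletions. The probe at spot 2611 fell in the tfbB (-1.20 ± 0.12), tbpA (-1.42 ± 0.12) and tfbD (-1.34 ± 0.12) deletions, the probe at spot 59 in the tbpD deletion (-1.11 ± 0.21), and the 2 in the tbpC deletion were at spots 5201 (-0.76 ± 0.12) and 4869 (-0.47 ± 0.11), all chosen after their values were seen. Without ura3 replicate 7 the tbpA, tfbB and tfbD counts became 24, 22 and 21, and without ura3 replicate 8 they became 24, 33 and 24. Without single cultures of the strain they were 124 (tbpA replicate 1), 37 (tbpA replicate 6), 63, 35 and 59 (tfbB replicates 1, 2 and 5), and 32 and 29 (tfbD replicates 4 and 5). The tbpD count was 5, 5, 4 and 5 without ura3 replicates 7 and 8 and tbpD replicates 3 and 5, and the tbpC count lay between 1 and 6, with 5 and 6 without its replicates 2 and 6 and 1 without its replicates 1, 4 and 5 or ura3 replicates 8 and 9. These numbers rest on few control cultures. Leaving out tfbA expression replicate 7, a culture of run 1 in the same fit, also moved the tbpA and tbpC counts, as given below. After centring and quantile normalization the tbpA, tfbB and tfbD counts were 9, 8 and 5, where 2 choices changed together. The 2 dye orientations of run 2 opposed each other weakly (-0.108). With culture RNA in channel 1 only the counts were 2 in tbpA, 5 in tfbB, 3 in tfbD, 0 in tbpD and 1 in tbpC, and in channel 2 only 180, 163, 174, 159 and 40, so these counts depended on the dye orientation.

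Expression of tbpD changed the most named genes among the strains with a vector control in their run (n = 6 and 6). hisD (0.55 ± 0.14) and hisF (0.46 ± 0.087) of histidine synthesis and eno (0.46 ± 0.17) were higher, while dpsA, which encodes an iron-binding protein that protects DNA (-0.47 ± 0.12), gdhB (-0.45 ± 0.15) and rimI (-0.23 ± 0.086) were lower. Higher in tbpB expression (n = 6) were gdhA2 (0.42 ± 0.12), cca, which adds the 3' end to tRNA (0.34 ± 0.099), and pyrB, the catalytic subunit of aspartate carbamoyltransferase (0.32 ± 0.11). Lower there were gdhB (-0.63 ± 0.15), thiC (-0.60 ± 0.21) and dpsA (-0.44 ± 0.12). Both strains shared lower gdhB, dpsA and cheB (-0.36 and -0.25) and higher cysS (0.28 and 0.39) and hisD (0.40 in tbpB expression). Of 100 splits of the tbpB and vector cultures, the real one included, 7 called at least as many probes as the real one. The highest called 487, so chance stays open for the tbpB count. With 1 culture left out at a time, hisD, hisF and dpsA in tbpD expression and gdhB in tbpB expression passed in 12 of 12 fits, while eno and rimI in tbpD expression passed in 4 and 3, gdhB there in 7, and pyrB and thiC in tbpB expression in 3 and 5. Against the other strains of run 3, hisF (0.30 ± 0.067), dpsA (-0.29 ± 0.096) and hisI (0.33 ± 0.051) differed in tbpD expression, and gdhB (-0.47 ± 0.12) and pyrB (0.41 ± 0.085) in tbpB expression. Of the other genes named for these strains against the vector control, hisD, rimI and cysS in tbpD and cca and cheB in tbpB expression were called there too. The genes eno, gdhB and cheB in tbpD and gdhA2, thiC, dpsA, cysS and hisD in tbpB expression were not.

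Expression of tbpC (n = 5) raised cmk (0.61 ± 0.13) and aspS (0.30 ± 0.076), which passed in 11 and 8 of 11 fits with a culture left out, and expression of tfbD (n = 6) raised htr7, a transducer gene (0.40 ± 0.11, 8 of 12 fits). limma called 341 probes in tbpD (228 higher, 113 lower), 179 in tbpB (68 and 111), 28 in tbpC (18 and 10), 46 in tfbD (33 and 13) and 20 in tfbE expression (4 and 16). Unnamed probes, chosen after their values were seen, differed more than named genes. In tbpD, tfbD and tfbE expression these include spots 5161 (-1.36 ± 0.20), 5161 (-1.92 ± 0.20) and 4433 (-2.54 ± 0.17). In tbpB expression they include spots 1605 (-2.055 ± 0.425) and 5171 (1.45 ± 0.099), and in tbpC expression spot 1645 (1.68 ± 0.12). No named gene passed in tbpA, tbpE, tbpF or tfbE expression, where limma called 6, 2, 6 and 20 probes, and 71, 98, 108 and 75 at an unadjusted p under 0.05. The 2 in tbpE expression were at spots 3789 (0.34 ± 0.078) and 4299 (-0.62 ± 0.14), chosen after their values were seen, and with a culture left out the count there was 0 or 1 in 9 fits, those without vector replicates 7, 8, 9 and 10 (1, 0, 0 and 1) and tbpE replicates 1 to 5 (0, 1, 0, 0 and 1). In tbpF expression vector replicates 8 and 9 and tbpF replicates 1 and 2 each gave 3. No list passed in these 8 strains (camera, 72 tests, 0 with an estimated correlation and 0 by fry). With centred and quantile normalized arrays, where 2 choices changed together, the share of higher calls went from 66.9% to 42.9% in tbpD, from 38.0% to 7.8% in tbpB, from 64.3% to 51.3% in tbpC and from 71.7% to 48.5% in tfbD expression, with 333, 51, 39 and 97 calls. Leaving out vector replicate 11 gave 100 calls in tbpB expression and 18 in tbpC expression, where vector replicate 12 and tbpC replicates 2 and 4 gave 16, 18 and 17, and in tfbD expression vector replicate 3 and tfbD replicate 5 gave 28 and 30.

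The tbpB and tbpD expression strains share their 6 vector cultures. They had 30 higher probes in common (7.50 for independent lists) and 56 lower (6.07). Their fold changes correlated at r = 0.644 across probes with a covariance of 0.0289, against r = 0.558 and a covariance of 0.00885 simulated with no effect and shared controls. With the controls split between them r was 0.518 and 0.558, and the covariances were 0.0240 and 0.0254.

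**Figure D3:**
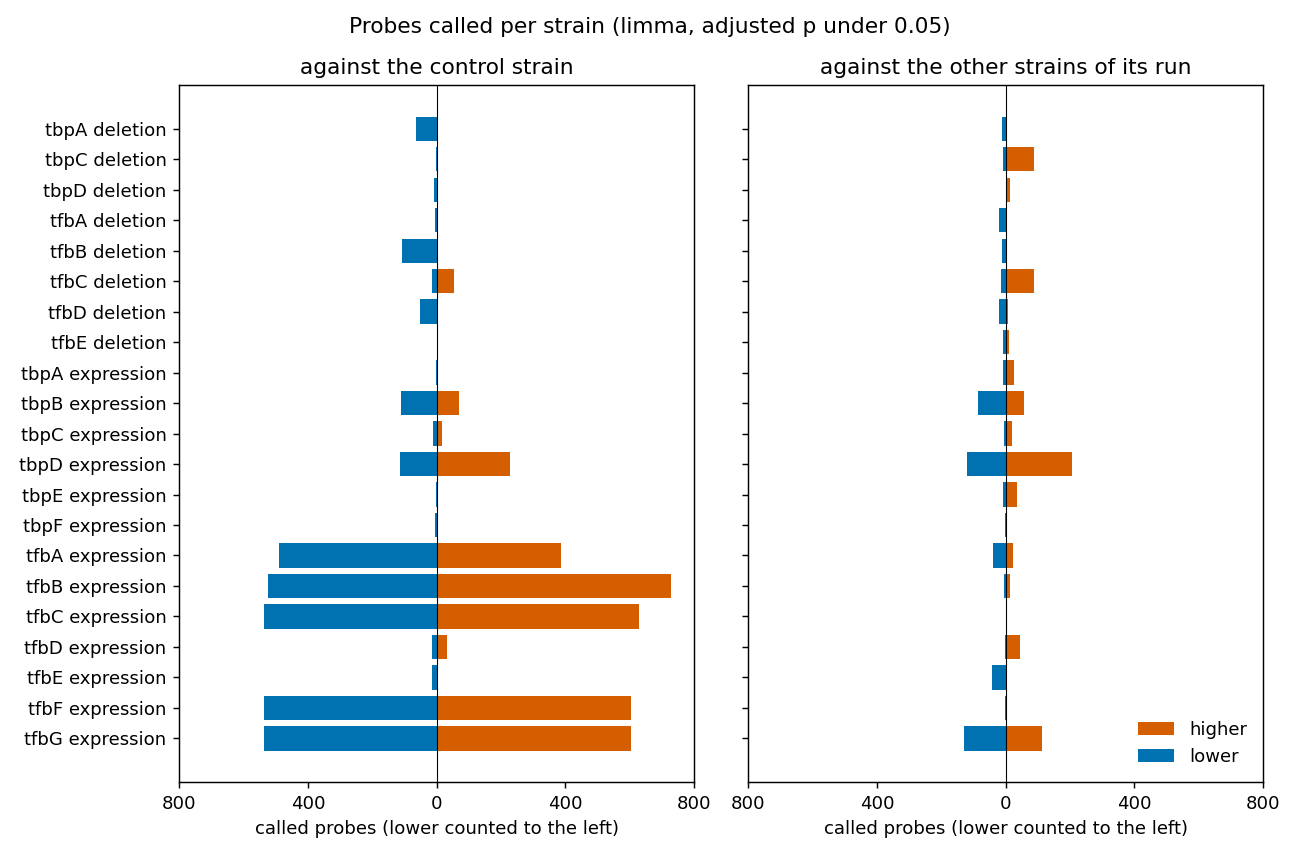
Number of called probes per strain (limma, adjusted p under 0.05), higher to the right and lower to the left, against the control strain (left panel) and against the other strains of the same run (right panel). The tfbB expression strain has 1253 calls against the vector controls of other runs and 18 against the other strains of run 1, while tbpD expression has 341 and 327.

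The 5 expression strains of run 1 were compared with the vector cultures of runs 3 and 5 (n = 12). Each of them had lower rpl12p, rpmC, secY and eno and higher htr7, purF and dpsA. In tfbB expression (n = 8) rpl12p (-1.43 ± 0.19), rpmC (-1.15 ± 0.17) and secY (-1.02 ± 0.14) were lower, and htr7 (0.73 ± 0.090), arcC (0.69 ± 0.21) and purF (0.68 ± 0.12) higher. In tfbC (n = 7) and tfbF expression (n = 8) the same 3 were lower (rpl12p -1.19 and -1.31), with argH (0.80 ± 0.15 in tfbC) and dpsA (0.72 ± 0.10 and 0.66 ± 0.098) higher. In tfbA expression (n = 8) argH was higher (0.77 ± 0.14) and phoU, a regulator of phosphate uptake, lower (-0.71 ± 0.15). In tfbG expression (n = 6) purF (0.97 ± 0.13), purM (0.67 ± 0.096) and thiD (0.54 ± 0.22) were higher and carB lower (-0.95 ± 0.22). The largest rise in each strain was at the unnamed spot 4007, from 1.70 ± 0.22 in tfbA to 2.325 ± 0.223 in tfbF expression, chosen after its values were seen. limma called 876 probes in tfbA (386 higher, 490 lower), 1253 in tfbB (729 and 524), 1163 in tfbC (628 and 535), 1140 in tfbF (605 and 535) and 1142 in tfbG expression (604 and 538). In tfbA expression, leaving out replicate 7 gave 1152 calls and turning its sign 1200, and rpl12p went from -0.83 to -1.28 and -1.34.

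The tRNA synthetase list was lower in all 5 strains, with 10 of 12 members called lower in tfbA and 9 of 12 in each of the others. The adjusted p lay between 0.00414 and 0.00438, with adjusted p = 0.196 with an estimated correlation in each, and 10, 10, 9, 9 and 9 passed adjusted over the list alone. Examples in tfbB expression are proS (-0.48 ± 0.059) and lysS (-0.50 ± 0.085). Chemotaxis was higher in tfbA, tfbB, tfbC and tfbF expression, with 6, 8, 8 and 7 of 10 members higher, 1 lower in each, and 7, 9, 10 and 8 called adjusted over the list alone (highest adjusted p = 0.0481, and adjusted p = 0.589 with an estimated correlation in each). In tfbB expression htr6 lay at 0.54 ± 0.072 and cheA at 0.54 ± 0.083. The tricarboxylic acid cycle was lower in tfbB expression, with 4 of 6 members called, among them sucD (-0.66 ± 0.15) and icd (-0.49 ± 0.090), and 4 adjusted over the list alone (adjusted p = 0.0436, and adjusted p = 0.589 with an estimated correlation). Purine synthesis was higher in tfbG expression, with 3 of 6 members called and 4 adjusted over the list alone (adjusted p = 0.0469, and adjusted p = 0.589 with an estimated correlation).

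Run and comparison cannot be told apart for these 5 strains, since run 1 held no control. Against the other strains of run 1 the counts were 62 in tfbA, 18 in tfbB, 3 in tfbC, 3 in tfbF and 244 in tfbG expression. Without tfbA expression replicate 7 they were 3, 15, 3, 3 and 339, and with its sign turned 5, 15, 3, 3 and 320, so most of the 62 in tfbA rested on that culture. Only tfbG expression had many named genes there, with argH (-0.66 ± 0.14), gdhB (-0.65 ± 0.12), cheB (-0.42 ± 0.071), dnaK (-0.31 ± 0.086) and cheA (-0.30 ± 0.081) lower and purF (0.37 ± 0.12) and purM (0.29 ± 0.086) higher. These 7 were called with the same signs without that culture and with its sign turned. By array number the tfbG arrays come first in run 1, across gaps in the numbers, so strain and array order cannot be told apart for tfbG. In tfbA expression rpl12p and rpmC turned sign there as labelled (0.37 and 0.20) but not without replicate 7 (-0.085 and -0.15), and purF did in both (-0.23 and -0.16, not called without it). Fold changes of the 5 strains correlated with each other at a mean r of 0.923 across probes, against 0.408 simulated with shared controls and no effect, and at 0.865 with the controls split. The mean covariance was 0.117, against 0.00394 simulated. Without tfbA expression replicate 7 the mean r was 0.933, 0.882 with the controls split, and the mean covariance 0.131, and with its sign turned they were 0.933, 0.882 and 0.131.

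For the 8 factors with both a deletion and an expression strain, the last comparison asked whether the changes were opposite. Fold changes correlated across probes, which are not independent replicates, at r = -0.35 for tbpD (rho -0.37), -0.34 for tfbB (rho -0.37), -0.22 for tbpC (rho -0.21), -0.15 for tfbD (rho -0.21) and -0.090 for tbpA (rho -0.10). For tfbA r was 0.44 (rho 0.46), for tfbC 0.057 (rho 0.031) and for tfbE 0.058 (rho 0.025). All factors with a negative r had their deletion in run 2, against the same ura3 cultures, so these values are not independent. All with a positive r had theirs in run 4, so the sign cannot be told apart from the run of the deletion. With controls of all runs pooled, the values that moved were 0.12 for tbpC, -0.026 for tbpD, 0.024 for tfbA and -0.12 for tfbC. The SE from leaving out cultures was 0.22 for tbpD, 0.24 for tfbB and 0.19 for tfbA, and only tfbA lay beyond 2 SE from 0. The tfbA expression strain is one of run 1, and against the other strains of its run and of the deletion's run r was -0.18, though 0.11 without tfbA expression replicate 7 and 0.054 with its sign turned, where the first r was 0.45 and 0.44. In the same comparison r was -0.32 for tfbB (-0.23 and -0.22) and -0.091 for tfbC (-0.074 and -0.083). In tfbB 61 probes were called in both strains, 58 of them in opposite directions, against 66.7 and 38.3 for independent lists, and in tfbC 35, 14 of them opposite, against 38.3 and 18.3. Both expression strains belong to run 1, so run and factor cannot be told apart in these called pairs.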

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

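Among the tests given here, those of a reversed dye orientation and of chance values of the shared controls were chosen only after the results had been seen.

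The 5 expression strains of run 1 shared a shift against the vector cultures of other runs. Their median count fell from 1142 to 18 against the other strains of run 1, a ratio of 0.0158, and from 1184 to 3 without tfbA expression replicate 7, while the dye effect per probe correlated between run 1 and runs 3 and 5 at 0.876 and 0.849, much as between runs 3 and 5 (0.853). Denser late cultures are argued against as the whole source, since the SD of the mean shift over probes was 0.370 in early and mid cultures and 0.346 in all, a ratio of 1.07 (1.02 without that culture), although mean late OD600 was 0.927 against 0.844. The shift in early and mid cultures correlated at 0.856 across probes with the late against early change. A difference between array runs and an effect common to these strains cannot be told apart, because run 1 held no control strain, and the effect of the factors stays open as untested.

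In 1 late culture of tfbA expression (replicate 7, n = 8) the mean correlation with other cultures of its run and stage was -0.83, far from the nearest other value of 0.41. With its sign turned it correlated at 0.887 with the mean of the other late cultures of the strain, just under their own values of 0.898 to 0.917. As labelled, its highest correlation with any other strain and stage was 0.643, with mid wild type cultures. A reversed dye orientation of both arrays and a wrong label both stay open, as neither reached the value set for it and neither fell to the value that would exclude it. No biological explanation was tested.

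The deletion strains of run 2 shared changes against their 3 ura3 cultures. Their mean r was 0.720, against 0.679 simulated with shared controls and no effect, so r by itself separates little. Their mean covariance was 0.0257, which is 1.54 times the highest of 50 simulations with independent cultures and shared controls (0.0167) and 1.75 times the highest with the spread of run 2 alone (0.0147). Residual SD was not larger in run 2 (0.151 against 0.175 in all runs), so a larger spread is argued against. The simulations assume that cultures and probes vary independently, so they argue only against chance of that kind in the controls. A control culture that is off at many probes together was not simulated. Other splits of the same cultures called up to 220 probes, and in each run 2 deletion they left chance open. A structure among the run 2 cultures stays open beside the deletions themselves.

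Chance flags about 1 in 20 groups, and 3 of 75 tests of groups and measures gave a culture far from the others. The median log2 ratio of tbpB expression replicate 5 (late, n = 6) was 0.48, with the nearest culture at 0.095. That of vector control replicate 7 (early, n = 6) was 0.13, with the nearest at 0.012. The growth response differed between strain and run groups for 1172 probes by the test of the interaction in limma. A late culture of run 1 with no strain in the labels had 59 probes at least 2-fold from the late vector controls, 27 higher and 32 lower, where the 17 other late cultures of run 1 had from 19 to 230, with a median of 78.

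Other splits of the same cultures were counted for 26 comparisons. For strains and controls, labels were exchanged among the cultures of a comparison, in groups of the same sizes. For the growth stages, stage labels were exchanged within each strain and run group. For the interaction, residuals of the additive fit were exchanged among all cultures, and each exchange is counted here as a split. Splits of strains did not keep the growth stages balanced between the groups. In 19 comparisons under 5% of the splits, the real one included, reached the real count. This bound was not adjusted over the 26, so chance is less likely there but not excluded. The count was reached by 1 split, the real one, in late against early (1688, highest other 540), mid against early (1040, 567), the interaction (1172, 335), ura3 against wild type (10, 9) and vector against ura3 (580, 244). It was also 1 split for the tfbC deletion (68, 14) and for expression of tbpA (6, 2), tbpC (28, 17), tbpD (341, 126), tbpE (2, 1), tfbD (46, 13), tfbA (876, 777), tfbB (1253, 757), tfbC (1163, 787), tfbF (1140, 568) and tfbG (1142, 256). The bound was also met with 2 splits for the tfbA deletion (5, 5) and tbpF expression (6, 12) and with 4 for tfbE expression (20, 79). In these 3 another split reached or passed the real count. The bound was not met for the tbpA deletion (5 of 84 splits, 63, highest other 220), the tbpC deletion (13 of 84, 2, 162), the tbpD deletion (6 of 84, 9, 213), the tfbB deletion (4 of 56, 112, 161), the tfbD deletion (8 of 84, 57, 150), the tfbE deletion (7 of 100, 2, 24) and tbpB expression (7 of 100, 179, 487). For vector against ura3 and the 5 strains of run 1 the groups share no run with their controls, so a real split above all others does not separate run from strain. Splits that called several times the real count, as in the tbpA, tbpC, tbpD and tfbE deletions and in tfbE expression, may point to a structure of the samples. Unequal growth stages between the groups of a split were not ruled out as their source.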

How the results depend on the processing

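Tests chosen only after the results had been seen were zeros as values, the fits without or with turned tfbA expression replicate 7, the fit without tbpA deletion replicate 1, standard errors from each probe's own cultures, the wild type alone, each run alone, comparisons within run 1 without or with turned tfbA expression replicate 7, and runs 3 and 4 as 1 random block. Lists within runs with an estimated correlation, and each run or the wild type held out, were also chosen then. Of 899 recomputed counts and correlations, 638 stayed within 1.5 times the reported count or within the spread and 261 moved. Of 5161 recomputed values of named genes, 4391 had the reported direction and side of the threshold, 658 were no longer past it, 24 newly passed it and 88 turned sign. The late against early count moved only in the wild type alone and under the minimum of 2-fold among the alternatives run. For the moved values below the cause was not tested, except where the alternative itself removes probes or cultures. The alternative of correlating deletion with expression without plasmid genes and without the factor was not run, since no annotation of replicons was used here and the factors carry no symbol. No paired analysis was possible because replicate numbers follow the order of the records and pair no cultures. Zeros, whose source is not given in the sources used here, limit the data, and of 2688 probes only the 2085 with enough values were tested.

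With centred and quantile normalized arrays, called probes numbered 597 in mid against early and 17 in ura3 against wild type, and 9 in tbpA, 1 in tbpC, 1 in tbpD, 8 in tfbB, 114 in tfbC, 5 in tfbD and 5 in tfbE among the deletions, and 11 in tbpA, 51 in tbpB, 0 in tbpE, 3 in tbpF and 97 in tfbD among the expression strains. Passing lists numbered 2 (expression, control in run) and 5 (expression, no control in run). The r of deletion against expression was -0.066 for tfbE. With culture RNA in channel 1 only, called probes numbered 23 in ura3 against wild type and 362 in vector against ura3, and 2 in tbpA, 1 in tbpC, 0 in tbpD, 5 in tfbB, 3 in tfbD and 15 in tfbE among the deletions, and 3 in tbpA, 99 in tbpB, 177 in tbpD, 11 in tbpE, 15 in tbpF and 8 in tfbE among the expression strains. Passing lists numbered 3 (deletion), 1 (expression, control in run) and 6 (expression, no control in run). The r of deletion against expression was 0.13 for tbpA, 0.11 for tbpC, -0.054 for tbpD and 0.24 for tfbC. With culture RNA in channel 2 only, called probes numbered 29 in ura3 against wild type, and 180 in tbpA, 40 in tbpC, 159 in tbpD, 93 in tfbA, 123 in tfbC, 174 in tfbD and 37 in tfbE among the deletions, and 21 in tbpA, 601 in tbpB, 164 in tbpC, 574 in tbpD, 98 in tbpE, 142 in tbpF and 84 in tfbD among the expression strains. Passing lists numbered 4 (expression, control in run). The r of deletion against expression was 0.25 for tfbA and 0.22 for tfbD. Signs turned for leuS 0.013 in tfbA expression. With OD600 as a curve, called probes numbered 1 in tbpC deletion. Passing lists numbered 5 (growth). With a mean per strain and stage, called probes numbered 29 in ura3 against wild type, and 32 in tbpA, 13 in tbpC, 10 in tfbA, 62 in tfbB, 149 in tfbC and 10 in tfbE among the deletions, and 12 in tbpA, 333 in tbpB, 81 in tbpC, 24 in tbpE, 31 in tbpF and 90 in tfbD among the expression strains. Passing lists numbered 9 (deletion) and 6 (expression, no control in run). With weights per culture, called probes numbered 65 in ura3 against wild type, and 269 in tbpA, 12 in tbpC, 36 in tbpD, 31 in tfbA, 234 in tfbB, 337 in tfbC and 23 in tfbE among the deletions, and 16 in tbpA, 455 in tbpB, 112 in tbpC, 39 in tbpE, 56 in tbpF, 1345 in tfbA, 134 in tfbD and 32 in tfbE among the expression strains. Passing lists numbered 2 (deletion) and 7 (expression, no control in run). With medians of spots, called probes numbered 1 in tbpE expression. With a minimum of 2-fold, which by construction leaves fewer, called probes numbered 5 in mid against early, 73 in late against early, 4 in ura3 against wild type and 5 in vector against ura3, and 4 in tbpA, 0 in tbpC, 1 in tbpD, 0 in tfbA, 3 in tfbB, 5 in tfbC, 5 in tfbD and 0 in tfbE among the deletions, and 1 in tbpA, 5 in tbpB, 1 in tbpC, 4 in tbpD, 0 in tbpE, 0 in tbpF, 7 in tfbA, 64 in tfbB, 44 in tfbC, 1 in tfbD, 3 in tfbE, 53 in tfbF and 33 in tfbG among the expression strains. With controls of all runs pooled, called probes numbered 317 in tbpA, 259 in tbpC, 296 in tbpD, 298 in tfbA, 481 in tfbB, 447 in tfbC, 412 in tfbD and 218 in tfbE among the deletions, and 15 in tbpA, 270 in tbpB, 80 in tbpC, 15 in tbpE and 18 in tbpF among the expression strains. Passing lists numbered 1 (deletion) and 1 (expression, control in run). The r of deletion against expression was 0.12 for tbpC, -0.026 for tbpD, 0.024 for tfbA and -0.12 for tfbC. Against the other strains of the run, called probes numbered 12 in tbpA, 99 in tbpC, 14 in tbpD, 25 in tfbA, 15 in tfbB, 103 in tfbC, 30 in tfbD and 16 in tfbE among the deletions, and 33 in tbpA, 43 in tbpE, 62 in tfbA, 18 in tfbB, 3 in tfbC, 46 in tfbE, 3 in tfbF and 244 in tfbG among the expression strains. The 46 in tfbE expression come from its contrast with tfbD expression, the only other such strain of run 5. The tfbD count is the same contrast with its sign turned. Passing lists numbered 3 (deletion), 5 (expression, control in run) and 4 (expression, no control in run). The r of deletion against expression was -0.18 for tfbA and -0.091 for tfbC. Signs turned for htr7 -0.079, purF -0.23, rpmC 0.20, rpl12p 0.37, phoU 0.15, htr6 -0.088, cheR -0.090, cheA -0.082, proS 0.13, lysS 0.20 and leuS 0.031 in tfbA expression, lysS 0.094 in tfbB expression, htr7 -0.041 in tfbC expression, purF -0.082 and proS 0.0054 in tfbF expression and rpmC 0.11 in tfbG expression.

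With each strain fitted only with its control, called probes numbered 36 in tbpA, 16 in tbpD, 73 in tfbA, 297 in tfbB, 439 in tfbC, 28 in tfbD and 32 in tfbE among the deletions, and 13 in tbpA, 50 in tbpC, 35 in tbpE, 174 in tbpF, 392 in tfbA, 93 in tfbD and 51 in tfbE among the expression strains. With run 3 vector and run 4 ura3 cultures, called probes numbered 53 in vector against ura3. Signs turned for ndk -0.10, cbiT 0.075 and gdhA1 0.056 in vector against ura3. With run 5 vector and run 4 ura3 cultures, called probes numbered 28 in vector against ura3. Signs turned for hisD 0.011 in vector against ura3. With run as a random block, called probes numbered 45 in vector against ura3. With run as a random block and runs 3 and 4 as 1, called probes numbered 111 in vector against ura3. With zeros as values, called probes numbered 6 in tbpC deletion. Passing lists numbered 1 (expression, control in run). Without tfbA expression replicate 7 in any comparison, called probes numbered 95 in tbpA and 6 in tbpC among the deletions. Passing lists numbered 5 (growth). With the sign of that culture turned, called probes numbered 96 in tbpA and 6 in tbpC among the deletions. Passing lists numbered 5 (growth). Against the other strains of the run without tfbA expression replicate 7, called probes numbered 3 in tfbA, 15 in tfbB, 3 in tfbC, 3 in tfbF and 339 in tfbG among the expression strains. Between deletion and expression r was 0.11 for tfbA and -0.074 for tfbC. Signs turned for purF -0.16, phoU 0.023, cheR -0.016, proS 0.027 and lysS 0.072 in tfbA expression, purF -0.0093 and lysS 0.13 in tfbB expression, rpl12p 0.036, secY 0.011, htr7 -0.082 and alaS 0.0031 in tfbC expression, purF -0.10, rpmC 0.046, secY 0.028, htr7 -0.0020, proS 0.033 and serS 0.00068 in tfbF expression and rpmC 0.19, secY 0.017 and proS 0.0091 in tfbG expression. Against the other strains of the run with that culture turned, called probes numbered 5 in tfbA, 15 in tfbB, 3 in tfbC, 3 in tfbF and 320 in tfbG among the expression strains. Between deletion and expression r was 0.054 for tfbA and -0.083 for tfbC. Signs turned for purF -0.092, phoU 0.0067, cheR -0.0024, proS 0.046 and lysS 0.10 in tfbA expression, purF -0.026 and lysS 0.12 in tfbB expression, rpl12p 0.051, secY 0.0089 and htr7 -0.093 in tfbC expression, purF -0.12, rpmC 0.035, secY 0.025, htr7 -0.013, proS 0.028 and serS 0.0036 in tfbF expression and rpmC 0.18, secY 0.015 and proS 0.0045 in tfbG expression.

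In run 1 alone without that culture, called probes numbered 273 in mid against early. Signs turned for trpC 0.0097 and pyrI -0.11 in mid against early and thiD -0.41, cbiT -0.21, thiC -0.18, cbiG -0.18 and cbiQ -0.14 in late against early. In run 1 alone with that culture turned, called probes numbered 252 in mid against early. Signs turned for trpC 0.0097 and pyrI -0.11 in mid against early and thiD -0.38, cbiT -0.22, thiC -0.18, cbiG -0.17 and cbiQ -0.14 in late against early. Without tbpA deletion replicate 1 in any comparison, called probes numbered 124 in tbpA deletion. For the wild type means in a fit of all cultures, called probes numbered 964 in late against early and 93 in mid against early. Signs turned for pan1 -0.061 in mid against early. In run 1 alone, called probes numbered 82 in mid against early. Signs turned for trpC 0.0097 and pyrI -0.11 in mid against early and thiD -0.34, cbiT -0.12, thiC -0.11, cbiG -0.12 and cbiQ -0.10 in late against early. In run 2 alone, signs turned for carB -0.19, ppsA -0.019 and carA -0.28 in mid against early. In run 3 alone, called probes numbered 489 in mid against early. In run 4 alone, signs turned for carB -0.16 and carA -0.057 in mid against early. In run 5 alone, signs turned for pan1 -0.14 in mid against early. With an estimated correlation, passing lists numbered 2 (growth), 0 (deletion) and 0 (expression, no control in run). By fry, passing lists numbered 17 (growth), 0 (deletion) and 29 (expression, no control in run).

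With each culture left out in turn, called probes lay between 24 and 124 in tbpA deletion, 1 and 6 in tbpC deletion, 4 and 11 in tbpD deletion, 3 and 7 in tfbA deletion, 22 and 166 in tfbB deletion, 47 and 69 in tfbC deletion, 21 and 70 in tfbD deletion, 0 and 5 in tfbE deletion. For expression strains the bounds were 4 and 6 in tbpA, 100 and 198 in tbpB, 16 and 30 in tbpC, 237 and 347 in tbpD, 0 and 2 in tbpE, 3 and 6 in tbpF, 744 and 1152 in tfbA, 1173 and 1270 in tfbB, 1080 and 1192 in tfbC, 28 and 46 in tfbD, 17 and 20 in tfbE, 1063 and 1137 in tfbF, 1023 and 1152 in tfbG. For ura3 against wild type they were 8 and 13.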

Other observations

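The comparisons given here with other strains of a run were planned as an alternative, and the genes, spots and strains singled out were chosen after their values were seen. Expression of tbpE called 2 probes against the vector control, but 43 against the other strains of run 3. There the chemotaxis genes cheA (0.38 ± 0.082), cheY (0.37 ± 0.069), cheB (0.36 ± 0.071) and cheR (0.29 ± 0.068) were higher and cysS, cysteinyl-tRNA synthetase, lower (-0.26 ± 0.067), with n = 6. None of these genes was called in tbpE expression against the vector control. The other strains include tbpB and tbpD expression, where cheB was lower and cysS higher against that control. A change in tbpE expression and opposite changes in the other strains can therefore not be told apart.

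The growth response of several genes differed in size between strain and run groups, and differences between runs are part of this. The late minus early difference of thiD, a thiamine synthesis gene, ran from -0.60 in tfbF expression to 2.19 in the ura3 control of run 2, which has 1 early and 1 late culture, and it was -0.34 in run 1 alone (-0.41 without tfbA expression replicate 7), and that of carB, carbamoyl phosphate synthase, from -1.12 in the tbpD deletion to 1.06 in tbpD expression. For gdhA1, a glutamate dehydrogenase, it was positive in 13 of 26 strain and run groups and negative in 13, while hisG of histidine synthesis was positive in 26 of 26, from 0.13 in tfbB expression to 1.16 in the wild type.

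The 2 unnamed probes with the largest fall in the ura3 strain against the wild type were low in every strain derived from it and in some plasmid-bearing strains. The probe at spot 4433 had a mean ratio of -2.24 in the ura3 control of run 4 (n = 6) and -0.22 in the wild type (n = 6), and was also low in tbpA (-2.55), tfbE (-2.34) and tfbF expression (-2.23). The probe at spot 5161 had -2.12 and -0.56 in the same groups, and was also low in tbpD (-1.71), tfbD (-2.10) and tfbE expression (-1.96).

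Of the other cultures outside every comparison, a mid culture of run 4 and an early culture of run 3 without a strain in the labels each had 1 probe at least 2-fold from the control cultures of their run and stage, and the single tbpB deletion culture had 2. Pairs of control cultures differed by 2-fold at 0 to 2 probes.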
